A study of Mus musculus with 16 samples.

How the data were processed

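Total RNA of 16 MEF samples was hybridised with Cy3 label to Illumina BeadChip arrays, and scanned signals were exported with GenomeStudio 2011.1, as the labels state. The deposited signals are a bead intensity per probe on a linear scale, without background subtraction or normalization. The deposited detection columns are headed as a p-value but hold 1 minus the detection p-value, since bright probes carry values near 1, and they were turned round before use. The authors also deposited a table of log2 values. Comparison with the signals showed it to be the log2 signal minus the 75th percentile of its array and minus the median of its probe over the 16 arrays, and it served as an alternative.

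The deposited signal column of the Smad1-/- BMP2 array repeats that of the Smad1f/f BMP2 array in 100% of probes. The detection values beside it do not belong to the repeated signals (Spearman correlation across probes 0.950, against 0.989 for the array with the same signals). The signals of that array were therefore recovered from the log2 table, whose missing array constant was found from the 0.1 steps of the signals, and 99.9% of the recovered values lay within 0.01 of such a step. The recovered signals had a Spearman correlation of 0.992 with that array's detection values and of at most 0.947 with those of any other array. The same procedure, with its values rounded to the 0.1 step, was run on the other 15 arrays and returned 100% of their deposited signals.

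Of the 24613 probes, 20984 named 1 gene in the platform table, 1 named several and 3628 named none, for 15967 genes. Signals of all 16 arrays were background corrected, quantile normalized and log2 transformed with limma's neqc (offset 16). Probes detected (p under 0.05) on at least 2 arrays of a fit were kept, the brightest kept probe stood for its gene, and unnamed probes were tested as themselves. No library depth exists for arrays, and the number of arrays limits the precision.

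Groups and comparisons were taken from the labels before the data were examined, as were the gene lists, the alternatives and the rule for naming genes. Each comparison was a contrast of a limma fit (limma 3.58.1, R 4.3.3) with additive terms for the other factors, since each condition had 1 array. Within a set agent had a level for each combination of BMP2 and ADR, while the fits over all 16 arrays took ADR and BMP2 as separate terms. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 in a two-sided test. The BMP2 and ADR comparisons on the arrays labelled transformed, the genotype comparison and the genotype interactions used 8 arrays, those of the arrays labelled primary the other 8, and the 2 comparisons between the sets all 16. The difference in level is that of the 4 Smad1f/f arrays from the mean of the arrays at 8 h and 16 h. 19 gene lists, 460 of whose 528 entries matched a probe, were tested with camera at a preset correlation of 0.01 and at an estimated correlation, adjusted over the lists of each comparison. Named genes were the 10 highest and 10 lowest changes among genes that passed with 1 sign in every pair of arrays, or all that passed and the 5 with the smallest p-values where fewer than 10 passed, the 2 to 4 members per list with the highest absolute change, among those that passed if any did, and Smad1, Smad5, Trp53, Cdkn1a, Mdm2, Id1 and Id3. Smad5 and Trp53 had no named probe that was kept. Where a gene was undetected on all arrays of its lower side, its fold is given as a bound, from the lowest detected signal of those arrays.

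The fits were tested on simulated data, 1 draw per comparison, in which 200 random genes changed by 0.5, 1 or 2 on the log2 scale. Between 1.23% and 14.1% of the calls of a comparison were false at the threshold of 0.05. Alternatives were no background correction, median scaling, the authors' log2 values, no detection filter, detection on every array, the mean of the probes of a gene, a robust variance trend, a joint fit of all 16 arrays or of other terms, a log2 change of at least 1, and leaving out each array in turn. A block for the BeadChip slide was not run because the files name no slide. Counts were also taken over other splits of the arrays into groups of the same sizes as the real ones. Figures were drawn from the result tables with Python 3.11.15.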

Results

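Gene expression was measured in mouse embryonic fibroblasts (MEFs) on 16 Illumina BeadChip arrays, 1 array for each of 16 conditions, so no condition had a replicate. By their labels, 8 arrays came from MEFs transformed with oncogenic Ras and E1A, with the Smad1 gene either floxed (Smad1f/f) or deleted (Smad1-/-). These were untreated at 0 h or treated for 12 h with BMP2, with Adriamycin (ADR, doxorubicin, a poison of topoisomerase II that breaks DNA) or with both. The other 8 arrays were labelled as primary MEFs at passage 2, untreated or treated with the same agents for 8 h or 16 h. The sample titles give 100 ng/ml BMP2 and 0.3 uM ADR, while the design text gives 50 ng/ml BMP2 and 1 ug/ml doxorubicin, so the doses are uncertain. Between 40.1% and 46.8% of the 24613 probes were detected per array, and the number of arrays limits the precision. Every change below is a log2 fold change with the standard error (SE) of a limma fit. Its spread was estimated from departures from additive effects, because no condition was repeated. Within a set these effects were genotype or time and agent, with a level for each combination of agents. A response to ADR that differs with and without BMP2 is therefore not part of the SE within a set. Gene lists were tested with limma's camera against all other genes, and each list's adjusted p with the preset correlation is followed by that with an estimated one. The latter is tested on the residual degrees of freedom of the fit, from 2 or 3 within a set to 10 for the difference in level between the sets. A failure within a set can therefore reflect the small number of arrays as well as correlated genes.

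SMAD1, which carries BMP signals to the nucleus, had 1 detected probe. Its signal with the Smad1-/- label minus that with the Smad1f/f label was 0.0093 ± 0.13 (adjusted p = 0.993, 4 arrays against 4, higher in 3 of 4 pairs), and whether this probe lies in the deleted part of the gene is not known. Several marker genes did not follow the labels of the 2 sets of arrays. Col1a1, the main chain of fibroblast collagen, was at least 201-fold higher on the arrays labelled transformed Smad1f/f than on those labelled primary, and Thy1, a fibroblast surface protein, at least 207-fold higher. Both were undetected on all 8 arrays labelled primary. Of 2 keratins of simple epithelia, Krt18 was 51.9-fold lower on the Smad1f/f arrays and Krt7 higher, with a difference of 2.41 ± 0.48. The 8 epithelial markers went both ways, 2 higher and 3 lower (adjusted p = 0.744, or adjusted p = 0.920 with an estimated correlation), with 2 higher and 3 lower when adjusted over the list alone. All groups below are therefore named by their labels, as labels and not as checked identities.

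**Figure D1:**
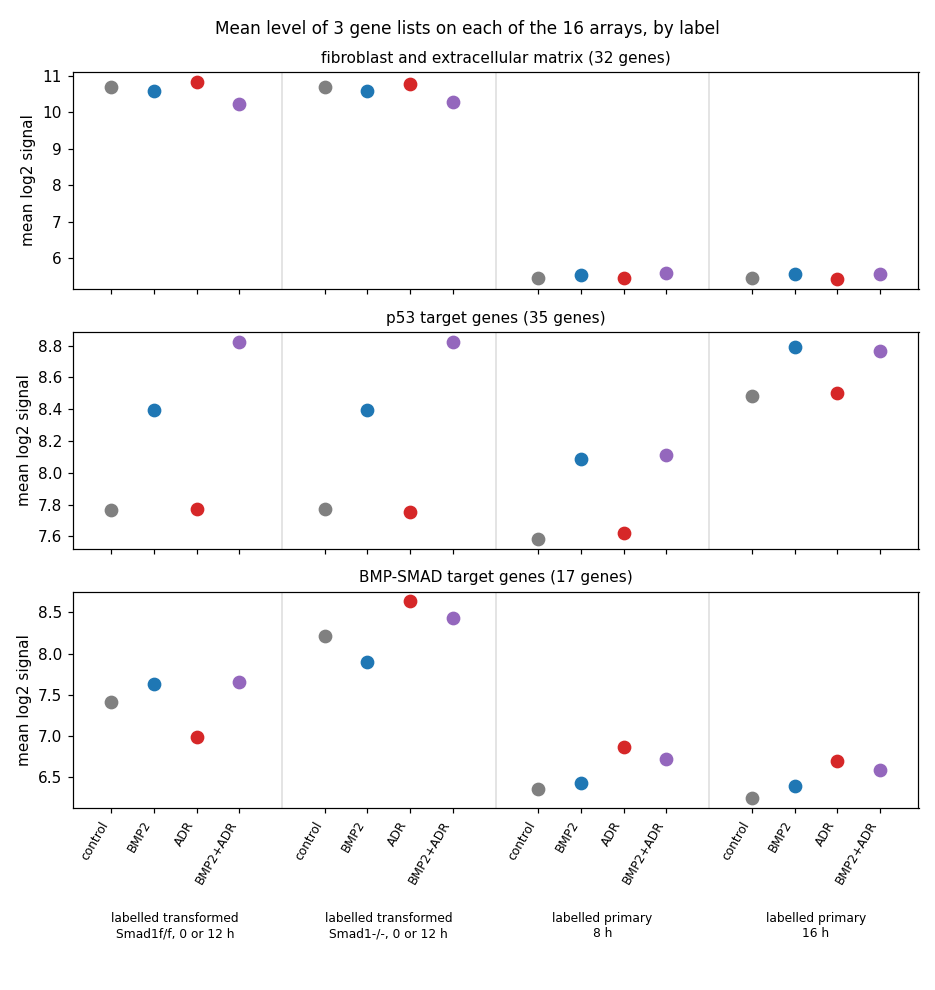
Mean log2 intensity of the members of 3 gene lists on each of the 16 arrays, 1 point per array, grouped by label. The fibroblast list had a median difference of 4.71 between the arrays labelled Smad1f/f and those labelled primary, with the higher values on the former.

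The first comparison asks what deletion of Smad1 does in the arrays labelled transformed. The BMP target genes had higher values with the Smad1-/- label, though no single gene passed over all genes tested. Id1 and Id3, which encode inhibitors of helix-loop-helix transcription factors and are direct targets of BMP signalling, differed by 1.45 ± 0.26 and 1.16 ± 0.19, higher in 4 of 4 pairs each (adjusted p = 0.216 and 0.211). The bone homeobox gene Dlx2 differed by 1.69 ± 0.32 and Sp7, the osteoblast factor osterix, by 2.13 ± 0.66. As a set the 17 measured BMP targets had a median of 0.80, with adjusted p = 1.39e-17, or adjusted p = 0.342 with an estimated correlation. Over all genes none of them passed, with 15 higher and 0 lower when adjusted over the list alone.

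Other lists moved less with the Smad1-/- label. The interferon response list had a median of -0.18 (adjusted p = 0.00214, or adjusted p = 0.372 with an estimated correlation), with Ifit3, an interferon-induced antiviral gene, at -0.46 ± 0.15. The immediate early genes had a median of 0.11 (adjusted p = 0.00223, or adjusted p = 0.342 with an estimated correlation), and Dusp6, a phosphatase of ERK, stood at 0.30 ± 0.091. Among TGF-beta targets the median was 0.075 (adjusted p = 0.00708, or adjusted p = 0.342 with an estimated correlation), with 2 higher and 0 lower when adjusted over the list alone. The 9 osteoblast and chondrocyte genes, which share Sp7 with the BMP list, had a median of 0.22 (adjusted p = 1.95e-05, or adjusted p = 0.342 with an estimated correlation). As drawn up, the osteoblast list also shares Runx2 and Alpl with the BMP list, the immediate early list Junb and the TGF-beta list Smad7. These lists are thus not independent of it. Cdkn1a, the p53 target that encodes p21, was at 0.088 ± 0.074 and Mdm2, the ubiquitin ligase of p53, at -0.10 ± 0.073, and the p53 list gave adjusted p = 0.971, or adjusted p = 0.987 with an estimated correlation. Adjusted over the list alone, 1 osteoblast gene was higher and 0 lower, and 0 genes of the interferon, immediate early and p53 lists passed. With limma, 0 of 10283 genes passed, 1027 had an unadjusted p under 0.05, and 10 passed with the authors' values, 5 with a robust variance trend and 25 in 1 fit of all 16 arrays. On simulated data 9.86% of the calls of this design were false.

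The next comparison sets the ADR label against no ADR on the arrays labelled transformed, 4 arrays against 4. Genes of DNA replication and mitosis fell. Tk1, the thymidine kinase of S phase, changed by -1.33 ± 0.071, Cdc45, a part of the replicative helicase, by -1.05 ± 0.089, and Top2a, the topoisomerase that doxorubicin poisons, by -1.16 ± 0.10, each lower in 4 of 4 pairs. Of the 27 G1/S and replication genes 23 fell and 0 rose (median -0.62, adjusted p = 1.56e-14, or adjusted p = 0.0763 with an estimated correlation), with 0 higher and 25 lower when adjusted over the list alone. Of the 22 G2/M genes 19 fell and 0 rose (median -0.66, adjusted p = 5.22e-13, or adjusted p = 0.0701 with an estimated correlation), with 0 higher and 20 lower when adjusted over the list alone. DNA repair genes fell in 10 of 24 cases and rose in 1 (median -0.22, or -0.19 with undetected genes at their bounds, adjusted p = 0.00435, or adjusted p = 0.125 with an estimated correlation), with 2 higher and 10 lower when adjusted over the list alone. Rad54l, a helicase of homologous recombination, changed by -0.94 ± 0.076. In the Smad1f/f and Smad1-/- pairs without BMP2 the mean of the G1/S list differed by -0.33 and -0.23, and in those with BMP2 by -1.12 and -0.98, with -0.32 and -0.35 and then -0.76 and -0.81 for G2/M genes.

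Histone, interferon and p53 target genes rose with the ADR label on these arrays on average, through the 2 pairs with BMP2. In the Smad1f/f and Smad1-/- pairs without BMP2 the list means differed by -0.013 and 0.033 for histone genes, 0.12 and -0.012 for interferon genes and 0.011 and -0.023 for p53 targets. In the pairs with BMP2 they differed by 0.76 and 0.70, 0.87 and 0.69 and 0.43 and 0.43 in the same order. The histone genes H4c8 and H2bc6 changed by 1.31 ± 0.069 and 1.30 ± 0.075. 20 of 30 histone genes rose and 5 fell (median 0.55, adjusted p = 1.83e-06, or adjusted p = 0.125 with an estimated correlation), with 22 higher and 5 lower when adjusted over the list alone. The interferon-induced GTPases Irgm2 and Igtp changed by 1.69 ± 0.17 and 1.33 ± 0.077, and 9 of 14 interferon genes rose while 1 fell (median 0.53, or 0.47 with undetected genes at their bounds, adjusted p = 3.16e-05, or adjusted p = 0.138 with an estimated correlation), with 10 higher and 1 lower when adjusted over the list alone. 13 of 33 p53 targets rose and 0 fell (median 0.17, adjusted p = 4.03e-04, or adjusted p = 0.125 with an estimated correlation), with 14 higher and 0 lower when adjusted over the list alone. Mdm2 rose by 0.45 ± 0.073 in 3 of 4 pairs and Gadd45a, a growth arrest gene induced by DNA damage, by 0.52 ± 0.086 in 4 of 4. Immediate early genes rose in 13 of 24 cases and fell in 0 (median 0.36, adjusted p = 4.03e-04, or adjusted p = 0.125 with an estimated correlation), with 16 higher and 2 lower when adjusted over the list alone, and Egr1, an early growth response factor, by 0.84 ± 0.068. Epithelial markers rose in 6 of 7 cases (median 0.70, or 0.58 with undetected genes at their bounds, adjusted p = 0.00155, or adjusted p = 0.125 with an estimated correlation), with 6 higher and 0 lower when adjusted over the list alone. These 2 lists also moved through the pairs with BMP2, by 0.60 and 0.54 for immediate early genes and 1.23 and 1.24 for epithelial markers, against -0.018 and 0.0044 and 0.056 and -0.072 without it. Mmp3, a matrix protease in the cytokine list, fell by 1.64 ± 0.17.

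In all, 2771 of 10283 genes passed with the ADR label, 1448 higher and 1323 lower, and 1818 of them had the same sign in every pair. Because the untreated arrays are from 0 h and the ADR arrays from 12 h, the 2 pairs without BMP2 also differ in time, and the difference between pairs with and without BMP2 was not tested. The count was 1638 without the untreated Smad1f/f array, 1682 without the untreated Smad1-/- array, 1826 without the Smad1-/- BMP2 array, and 1641 and 1794 without the Smad1f/f and Smad1-/- arrays of both agents.

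The comparison free of that time difference adds ADR to BMP2 at 12 h, 2 arrays against 2. Its 4 arrays are among the 8 of the ADR comparison above, so it is no second observation. Replication genes fell and histone genes rose. Krtap1-5, a keratin-associated protein, was at least 8.57-fold higher with both agents, and Eef1a2, a translation elongation factor of muscle and neurons, rose 11.7-fold. Mcm2, a subunit of the replicative helicase, changed by -2.04 ± 0.10 and Tk1 by -2.21 ± 0.10, and 24 of 27 G1/S genes fell while 0 rose (median -1.02, adjusted p = 1.00e-12, or adjusted p = 0.0836 with an estimated correlation), with 0 higher and 25 lower when adjusted over the list alone. G2/M genes fell in 21 of 22 cases (median -0.91, adjusted p = 1.13e-10, or adjusted p = 0.0836 with an estimated correlation), with 0 higher and 21 lower when adjusted over the list alone. Histone genes rose in 22 of 30 and fell in 5 (median 0.89, adjusted p = 1.07e-07, or adjusted p = 0.115 with an estimated correlation), with 22 higher and 5 lower when adjusted over the list alone. Among p53 targets 15 of 33 rose and 0 fell (median 0.28, adjusted p = 1.60e-05, or adjusted p = 0.0836 with an estimated correlation), with 15 higher and 0 lower when adjusted over the list alone. Interferon genes rose in 11 of 14 and fell in 1 (median 1.04, or 0.91 with undetected genes at their bounds, adjusted p = 1.37e-05, or adjusted p = 0.126 with an estimated correlation), with 11 higher and 1 lower when adjusted over the list alone. Immediate early genes rose in 16 of 24 and fell in 1 (median 0.83, adjusted p = 5.95e-05, or adjusted p = 0.115 with an estimated correlation), with 16 higher and 1 lower when adjusted over the list alone. Mdm2 changed by 0.95 ± 0.10, Cdkn1a by 0.65 ± 0.10 and Perp, a p53 target of desmosomes, by 1.57 ± 0.16, each higher in 2 of 2 pairs. Id1 stood at 0.48 ± 0.36 (adjusted p = 0.339).

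Epithelial markers rose and fibroblast genes fell when ADR was added to BMP2. Krt7 changed by 2.51 ± 0.23 and St14, an epithelial surface protease, by 2.51 ± 0.16, each higher in 2 of 2 pairs. 6 of 7 epithelial markers rose and 1 fell (median 1.35, adjusted p = 0.00122, or adjusted p = 0.115 with an estimated correlation), with 6 higher and 1 lower when adjusted over the list alone. Elastin, Eln, changed by -1.27 ± 0.094 and Igfbp4, an IGF binding protein, by -1.01 ± 0.12, each lower in 2 of 2 pairs. 11 of 32 fibroblast genes fell and 2 rose (median -0.19, adjusted p = 0.0108, or adjusted p = 0.126 with an estimated correlation), with 2 higher and 13 lower when adjusted over the list alone. DNA repair genes fell in 10 of 24 and rose in 2 (median -0.31, or -0.28 with undetected genes at their bounds, adjusted p = 0.0347, or adjusted p = 0.180 with an estimated correlation), with 3 higher and 11 lower when adjusted over the list alone, a preset call that ended without the Smad1f/f array of both agents, at -0.18. NF-kB and cytokine genes rose in 8 of 18 and fell in 1 (median 0.53, or 0.50 with undetected genes at their bounds, adjusted p = 0.0420, or adjusted p = 0.382 with an estimated correlation), with 9 higher and 2 lower when adjusted over the list alone. This preset call ended without the Smad1-/- BMP2 array, at 0.42, without the Smad1-/- array of both agents, at 0.31, and with median scaling, at 0.71. 3673 genes passed, 1879 higher and 1794 lower. With median scaling 70.6% of those that passed were higher, against 51.2%, and the median of all genes moved from -0.022 to 0.096. The count fell to 2189 and 2199 without the Smad1f/f and Smad1-/- BMP2 arrays, and to 2004 and 2137 without the Smad1f/f and Smad1-/- arrays of both agents.

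BMP2 for 12 h against the untreated arrays at 0 h, 2 arrays against 2 on the arrays labelled transformed, asks for the BMP2 response together with 12 h of culture. p53 target genes rose while genes of the integrated stress response fell. Pmaip1, the apoptosis gene Noxa, changed by 2.63 ± 0.12, Fas, a death receptor, by 2.57 ± 0.12, and Mdm2 by 0.57 ± 0.10, and Acer2, a ceramidase, was at least 19.6-fold higher. 19 of 33 p53 targets rose and 1 fell (median 0.51, or 0.38 with undetected genes at their bounds, adjusted p = 1.92e-04, or adjusted p = 0.281 with an estimated correlation), with 20 higher and 2 lower when adjusted over the list alone. Trib3, a pseudokinase induced by ATF4, changed by -3.28 ± 0.12 and Atf4 itself, the transcription factor of that response, by -2.06 ± 0.13. In this stress list 12 of 23 members fell and 3 rose (median -0.41, or -0.33 with undetected genes at their bounds, adjusted p = 0.0404, or adjusted p = 0.320 with an estimated correlation), with 3 higher and 12 lower when adjusted over the list alone. Ccn2, a matricellular protein and TGF-beta target, changed by -2.49 ± 0.11, and 6 of 13 TGF-beta targets fell (median -0.28, adjusted p = 0.0404, or adjusted p = 0.320 with an estimated correlation), with 0 higher and 6 lower when adjusted over the list alone. The preset calls of the stress and TGF-beta lists ended without any 1 of the 4 arrays labelled ADR, at unchanged medians, and that of the TGF-beta list also without the untreated Smad1f/f array, at a median of -0.18. With detection on every array neither list kept its call. Mdm2 did not pass in 1 fit of all 16 arrays. Endothelial markers rose: Sox18, an endothelial transcription factor, was at least 1.98-fold higher and Mmrn2, an endothelial matrix protein, changed by 1.30 ± 0.21. 6 of 9 rose and 0 fell (median 0.66, or 0.60 with undetected genes at their bounds, adjusted p = 0.0163, or adjusted p = 0.320 with an estimated correlation), with 6 higher and 0 lower when adjusted over the list alone, and with detection on every array the preset call ended at a median of 0.23. BMP targets went both ways, 3 up and 3 down of 17 (adjusted p = 0.928, or adjusted p = 0.946 with an estimated correlation), with 3 higher and 2 lower when adjusted over the list alone: Id3 changed by -1.64 ± 0.26, Id1 stood at -0.35 ± 0.36 (adjusted p = 0.467), and Dlx3, a homeobox gene, was at least 5.21-fold higher. Icam1, an adhesion molecule, rose 10.8-fold. 4776 genes passed, 2329 higher and 2447 lower. With median scaling 27.8% of those that passed were higher, against 48.8%, and the median of all genes moved to -0.19.

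BMP2 added to ADR at 12 h, again 2 arrays against 2, gave the highest number of genes within the arrays labelled transformed. Dcxr, a carbonyl reductase and p53 target, rose by 3.28 ± 0.11, Fas by 3.22 ± 0.12, Mdm2 by 1.56 ± 0.10 and Cdkn1a by 1.02 ± 0.10, each in 2 of 2 pairs. 24 of 33 p53 targets rose and 1 fell (median 1.02, or 0.96 with undetected genes at their bounds, adjusted p = 6.99e-08, or adjusted p = 0.125 with an estimated correlation), with 24 higher and 1 lower when adjusted over the list alone. Psmb9, an immunoproteasome subunit, was at least 10.6-fold higher, and 10 of 14 interferon genes rose and 1 fell (median 0.90, or 0.88 with undetected genes at their bounds, adjusted p = 3.51e-04, or adjusted p = 0.186 with an estimated correlation), with 11 higher and 1 lower when adjusted over the list alone. Histone genes rose in 23 of 30 and fell in 5 (median 1.20, or 1.18 with undetected genes at their bounds, adjusted p = 5.61e-06, or adjusted p = 0.149 with an estimated correlation), with 23 higher and 5 lower when adjusted over the list alone. Mcm2 changed by -2.42 ± 0.10 and Top2a by -2.59 ± 0.15, and 20 of 27 G1/S genes fell and 2 rose (median -0.71, adjusted p = 5.95e-04, or adjusted p = 0.161 with an estimated correlation), with 4 higher and 20 lower when adjusted over the list alone. Of G2/M genes 15 of 22 fell and 2 rose (median -0.57, adjusted p = 0.00389, or adjusted p = 0.149 with an estimated correlation), with 2 higher and 16 lower when adjusted over the list alone.

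Stress and matrix genes fell with BMP2 on ADR. Trib3 changed by -3.93 ± 0.12 and Chac1, another ATF4 target, by -2.26 ± 0.14, and 18 of 23 stress genes fell and 2 rose (median -0.83, adjusted p = 2.32e-04, or adjusted p = 0.149 with an estimated correlation), with 2 higher and 18 lower when adjusted over the list alone. Pdgfrb, a PDGF receptor of fibroblasts, changed by -2.27 ± 0.13 and Eln, elastin, by -1.47 ± 0.094, and 17 of 32 fibroblast genes fell and 2 rose (median -0.53, adjusted p = 0.00358, or adjusted p = 0.149 with an estimated correlation), with 2 higher and 17 lower when adjusted over the list alone. Epithelial markers rose in 6 of 7 cases (median 2.36, or 1.92 with undetected genes at their bounds, adjusted p = 0.00533, or adjusted p = 0.161 with an estimated correlation), with 6 higher and 1 lower when adjusted over the list alone. BMP targets rose in 6 of 17 cases and fell in 2 (adjusted p = 0.355, or adjusted p = 0.781 with an estimated correlation), with 6 higher and 2 lower when adjusted over the list alone; Id1 stood at 0.51 ± 0.36 (adjusted p = 0.265) and Grem1, a secreted BMP antagonist, fell, with a change of -2.28 ± 0.13. 5873 genes passed, 2665 higher and 3208 lower.

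Whether the Smad1 genotype changes these responses was tested as a difference of differences. BMP targets had a higher response to the ADR label with Smad1-/- than with Smad1f/f, with a median of 0.60 over 17 genes (adjusted p = 6.37e-07, or adjusted p = 0.858 with an estimated correlation), with 2 higher and 0 lower when adjusted over the list alone. For BMP2 the same list had a median of -0.38 (adjusted p = 4.98e-07, or adjusted p = 0.868 with an estimated correlation), with 0 higher and 0 lower when adjusted over the list alone. Id1 was at 0.60 ± 0.51 for ADR and -1.13 ± 0.33 for BMP2, neither past the threshold (adjusted p = 0.882 and 0.793). For Cdkn1a the differences were 0.0042 ± 0.15 and 0.079 ± 0.15, and for Mdm2 -0.047 ± 0.15 and 0.040 ± 0.15. The osteoblast list, which shares members with the BMP list, had a median of 0.24 for ADR (adjusted p = 0.00949, or adjusted p = 0.858 with an estimated correlation), with 1 higher and 0 lower when adjusted over the list alone. This preset call ended without the Smad1f/f BMP2 array and without the Smad1-/- BMP2 array, at a median of 0.26 each, and with no detection filter, at 0.040. limma called 0 genes for ADR and 0 for BMP2, with 608 and 630 at an unadjusted p under 0.05. The fit of all 16 arrays called 1 and 0, and leaving out any 1 of the 4 arrays labelled ADR called 1 for ADR. Median scaling put the median of all genes for ADR at 0.11. On simulated data this design recovered 11.9% of differences of 0.5 and 98.5% of differences of 1 for ADR, and 14.1% of its calls were false, against 8.55% for BMP2. The changed genes there were drawn from all genes, whose median SE was 0.16 for ADR and 0.17 for BMP2. Id1 had an SE of 0.51 and 0.33, so that recovery does not carry over to it or to other genes with a high SE.

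On the arrays labelled primary, the ADR label was compared with its absence over 8 h and 16 h, 4 arrays against 4. BMP targets rose and p53 targets did not pass. Id1 changed by 1.18 ± 0.097, Id3 by 0.76 ± 0.080, Dlx2 by 1.02 ± 0.11 and Gata2, a haematopoietic transcription factor, by 0.82 ± 0.091, each higher in 4 of 4 pairs. 4 of 11 BMP targets rose and 0 fell (median 0.55, or 0.39 with undetected genes at their bounds, adjusted p = 5.68e-16, or adjusted p = 0.0751 with an estimated correlation), with 9 higher and 0 lower when adjusted over the list alone. Ltbp2, a latent TGF-beta binding protein, changed by 1.16 ± 0.11, and 2 of 9 TGF-beta targets rose (median 0.32, adjusted p = 1.92e-06, or adjusted p = 0.423 with an estimated correlation), with 5 higher and 0 lower when adjusted over the list alone. Sct, the hormone secretin, rose 3.58-fold. Ndrg1, a hypoxia-responsive gene, changed by -0.80 ± 0.099, Hk2, a hexokinase, by -0.65 ± 0.082, and Cdkn1c, the cell cycle inhibitor p57, by -0.69 ± 0.072, each lower in 4 of 4 pairs. Cdkn1a stood at 0.057 ± 0.11 (adjusted p = 0.933) and Mdm2 at 0.00012 ± 0.18 (adjusted p = 1.00). None of 35 p53 targets passed in limma (median 0.014, adjusted p = 0.673, or adjusted p = 0.774 with an estimated correlation), with 0 higher and 0 lower when adjusted over the list alone.

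In this comparison 28 of 9457 genes passed, 23 higher and 5 lower. The count depended on every array: it was 5, 2, 2 and 2 without the untreated, BMP2, ADR and combined arrays at 8 h, and 9, 4, 2 and 6 without those at 16 h. Of the genes named above only Sct passed without each array in turn. Id1, Id3, Dlx2, Ndrg1 and Cdkn1c did not pass in 1 fit of all 16 arrays. Fbln2, a matrix fibulin that passed with 0.59 ± 0.074, was at -0.12 without the combined array at 16 h. Alternative settings gave between 21 and 88 genes at the same threshold, and on simulated data 8.45% of the calls of this design were false.

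The BMP2 label on the arrays labelled primary, 4 arrays against 4, went with a wider response. Cryab, a small heat shock protein, rose 15.8-fold, Gpnmb, a transmembrane glycoprotein, 9.59-fold, and the homeobox gene Hoxc6 8.88-fold. Barx1, another homeobox gene, was at least 5.48-fold higher. Eng, the TGF-beta co-receptor endoglin, was at least 4.19-fold lower and Mdk, the growth factor midkine, at least 2.98-fold lower, each in 4 of 4 pairs. BMP targets split: Dlx2 rose by 1.35 ± 0.11, while Id2 changed by -1.18 ± 0.12 and Id1 by -0.52 ± 0.097, both lower in 4 of 4 pairs. Id1 did not pass in 1 fit of all 16 arrays. Id3 stood at -0.18 ± 0.080 (adjusted p = 0.159). Of 11 BMP targets 3 rose and 4 fell (adjusted p = 0.916, or adjusted p = 0.917 with an estimated correlation), with 3 higher and 4 lower when adjusted over the list alone. Smad1 rose by 0.62 ± 0.083 in 4 of 4 pairs.

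p53 targets and histone genes rose with the BMP2 label. Ephx1, an epoxide hydrolase, changed by 1.55 ± 0.097, Pmaip1 by 1.08 ± 0.096 and Cdkn1a by 0.98 ± 0.11, and 14 of 35 p53 targets rose and 1 fell (median 0.33, adjusted p = 3.63e-07, or adjusted p = 0.331 with an estimated correlation), with 18 higher and 1 lower when adjusted over the list alone. The linker histone gene H1f2 changed by 1.92 ± 0.18, and 14 of 27 histone genes rose and 0 fell (median 0.37, adjusted p = 1.11e-05, or adjusted p = 0.331 with an estimated correlation), with 14 higher and 0 lower when adjusted over the list alone. Of G2/M genes 7 of 24 fell and 0 rose (median -0.19, adjusted p = 0.00299, or adjusted p = 0.331 with an estimated correlation), with 0 higher and 8 lower when adjusted over the list alone. 1892 genes passed, 967 higher and 925 lower. The count was 1160 without the BMP2 array at 8 h, and 1180, 1173 and 1178 without the BMP2, ADR and combined arrays at 16 h.

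On the same arrays, BMP targets responded less to both agents than the sum of the single responses, with a median interaction of -0.32 over 11 genes (adjusted p = 1.76e-05, or adjusted p = 0.348 with an estimated correlation), with 0 higher and 0 lower when adjusted over the list alone. Id1 was at -0.47 ± 0.19 and Dlx2 at -0.73 ± 0.22, neither past the threshold (adjusted p = 0.810 and 0.775), and Cdkn1a was at -0.18 ± 0.22. The response to ADR at 16 h minus that at 8 h was -0.34 ± 0.16 for Id1, 0.13 ± 0.23 for Cdkn1a and -0.16 ± 0.39 for Mdm2, and the list with the smallest p, of muscle markers, gave adjusted p = 0.610, or adjusted p = 0.954 with an estimated correlation. limma called 0 and 0 genes for these 2 interactions, with 574 and 500 at an unadjusted p under 0.05, and the fit of all 16 arrays called 0 and 0. On simulated data differences of 1 were recovered in 85.1% and 80.6% of cases, and 6.62% and 8.76% of the calls were false.

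Between 8 h and 16 h, over the 4 agents of the arrays labelled primary, p53 targets rose and histone genes fell. Dcxr changed by 2.15 ± 0.099, Pidd1, a death domain protein, by 1.62 ± 0.15, Apaf1, the scaffold of the apoptosome, by 1.59 ± 0.16, and Cdkn1a by 1.13 ± 0.11, each higher in 4 of 4 pairs. 25 of 35 p53 targets rose and 0 fell (median 0.87, or 0.76 with undetected genes at their bounds, adjusted p = 6.12e-15, or adjusted p = 0.167 with an estimated correlation), with 28 higher and 1 lower when adjusted over the list alone. H2bc4 and H1f2, a core and a linker histone gene, changed by -2.33 ± 0.13 and -2.29 ± 0.18, and 22 of 27 histone genes fell and 0 rose (median -0.89, adjusted p = 1.65e-14, or adjusted p = 0.167 with an estimated correlation), with 0 higher and 23 lower when adjusted over the list alone. Trib3 changed by -1.44 ± 0.12 and 11 of 21 stress genes fell (median -0.27, adjusted p = 0.00148, or adjusted p = 0.199 with an estimated correlation), with 0 higher and 12 lower when adjusted over the list alone. G2/M genes rose in 9 of 24 cases (median 0.19, adjusted p = 9.97e-05, or adjusted p = 0.199 with an estimated correlation), with 9 higher and 0 lower when adjusted over the list alone, and Nusap1, a spindle protein, by 0.62 ± 0.083. 2783 genes passed, 1179 higher and 1604 lower. With median scaling 77.0% of those that passed were higher, against 42.4%, with a median of all genes of 0.069 in place of -0.047. With the authors' values 4353 genes passed with 25.4% higher and a median of all genes of -0.11. The count was 1817, 1672, 1658 and 1822 without the untreated, BMP2, ADR and combined arrays at 8 h, and 1804, 1693 and 1677 without the untreated, BMP2 and ADR arrays at 16 h.

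Whether the response to the ADR label differed between the 2 sets was tested over all 16 arrays, as the response on arrays labelled transformed minus that on arrays labelled primary. The pairs labelled primary are matched in time, while those labelled transformed without BMP2 set 12 h against 0 h. Time and the response to ADR can thus not be told apart for these genes and lists. The difference was negative for cell cycle genes and for Mmp3, at -1.67 ± 0.20. Ndc80, a kinetochore protein, was at -1.17 ± 0.14, Dhx9, an RNA helicase, at -1.10 ± 0.14, and Dbp, a clock output transcription factor, at 1.30 ± 0.18, each with 1 sign in 16 of 16 pairs of differences. These 16 cross the 4 ADR differences of one set with the 4 of the other, so they are not 16 separate observations. The G1/S list had a median of -0.68 (adjusted p = 4.56e-15, or adjusted p = 0.261 with an estimated correlation) and 2 of 27 members passed as lower, with 0 higher and 23 lower when adjusted over the list alone. The G2/M list had a median of -0.59 (adjusted p = 1.85e-15, or adjusted p = 0.114 with an estimated correlation) and 2 of 24 passed as lower, with 0 higher and 19 lower when adjusted over the list alone. For histone genes the median was 0.48 (adjusted p = 7.07e-04, or adjusted p = 0.343 with an estimated correlation), with 13 higher and 4 lower when adjusted over the list alone, and for interferon genes 0.50 (adjusted p = 7.37e-04, or adjusted p = 0.321 with an estimated correlation), with 7 higher and 0 lower when adjusted over the list alone. On the arrays labelled transformed the histone and interferon responses lie in the pairs with BMP2, as given above. The p53 list had a median of 0.14 (adjusted p = 0.0352, or adjusted p = 0.449 with an estimated correlation), with 1 higher and 0 lower when adjusted over the list alone. That preset call ended without either BMP2 array or either combined array of the set labelled transformed, and without the BMP2 or ADR array at 8 h or the untreated or combined array at 16 h, with medians of 0.096, 0.075, 0.085, 0.10, 0.086, 0.099, 0.10 and 0.066 in that order. Id1 was at -1.12 ± 0.35 (adjusted p = 0.117).

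106 of 10982 genes passed in this comparison, 43 higher and 63 lower, and 1 passed without a term for a different BMP2 response in the 2 sets. Leaving out any 1 of the 16 arrays moved the count by over 1.5 times: it was 271 and 310 without the untreated Smad1f/f and Smad1-/- arrays and 347 and 365 without their ADR arrays, and between 16 and 40 without any of the other 12, the lowest without the combined array at 8 h. Median scaling gave 300 genes, 13.3% of them higher, against 40.6%.

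The last comparison sets the level of each gene on the 4 arrays labelled transformed Smad1f/f against the 8 labelled primary. Extracellular matrix genes were higher on the Smad1f/f arrays. Acta2, smooth muscle actin, was at least 638-fold higher, Lox, which crosslinks collagen, at least 449-fold, and Igf2, a fetal growth factor, 682-fold, each in 8 of 8 pairs. Each Smad1f/f array was paired with the arrays of the same agent at 8 h and at 16 h, so these pairs are not independent. Il24, a cytokine, was at least 88.1-fold lower. 31 of 32 fibroblast genes were higher and 0 lower (median 4.71, or 4.69 with undetected genes at their bounds, adjusted p = 1.26e-24, or adjusted p = 0.0157 with an estimated correlation), with 31 higher and 0 lower when adjusted over the list alone. Among TGF-beta targets 11 of 13 were higher and 1 lower (median 2.10, adjusted p = 1.67e-06, or adjusted p = 0.0390 with an estimated correlation), with 11 higher and 1 lower when adjusted over the list alone. Ccl7, a chemokine, was at least 44.8-fold higher, and 16 of 20 NF-kB and cytokine genes were higher and 2 lower (median 1.79, or 1.68 with undetected genes at their bounds, adjusted p = 9.99e-05, or adjusted p = 0.0329 with an estimated correlation), with 16 higher and 2 lower when adjusted over the list alone. The BMP receptor and regulator list gave 8 higher and 2 lower of 18 (median 0.57, or 0.41 with undetected genes at their bounds, adjusted p = 0.00675, or adjusted p = 0.0390 with an estimated correlation), with 8 higher and 2 lower when adjusted over the list alone, and Bmp4, a ligand, differed by 4.09 ± 0.16.

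Proliferation genes were lower on the Smad1f/f arrays. Mcm10, a replication factor, differed by -2.48 ± 0.21 and Fancd2, of the Fanconi repair pathway, by -2.24 ± 0.14. 25 of 27 G1/S genes were lower and 0 higher (median -1.60, adjusted p = 2.28e-07, or adjusted p = 0.301 with an estimated correlation), with 0 higher and 26 lower when adjusted over the list alone. G2/M genes were lower in 22 of 24 cases (median -1.13, or -1.08 with undetected genes at their bounds, adjusted p = 7.99e-06, or adjusted p = 0.325 with an estimated correlation), with 0 higher and 23 lower when adjusted over the list alone, and DNA repair genes in 24 of 26 (median -1.03, or -0.98 with undetected genes at their bounds, adjusted p = 2.28e-07, or adjusted p = 0.0157 with an estimated correlation), with 0 higher and 25 lower when adjusted over the list alone. Histone genes were higher in 20 of 31 and lower in 8 (median 1.05, or 1.01 with undetected genes at their bounds, adjusted p = 0.00266, or adjusted p = 0.350 with an estimated correlation), with 20 higher and 8 lower when adjusted over the list alone. Stress genes were higher in 11 of 23 and lower in 1 (median 0.61, or 0.27 with undetected genes at their bounds, adjusted p = 0.00675, or adjusted p = 0.379 with an estimated correlation), with 11 higher and 1 lower when adjusted over the list alone. Mdm2 differed by -1.54 ± 0.20, lower in 8 of 8 pairs. 6970 of 10982 genes passed, 2959 higher and 4011 lower. With probes detected on every array 4533 passed, and without the arrays labelled ADR 4464.

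**Figure D2:**
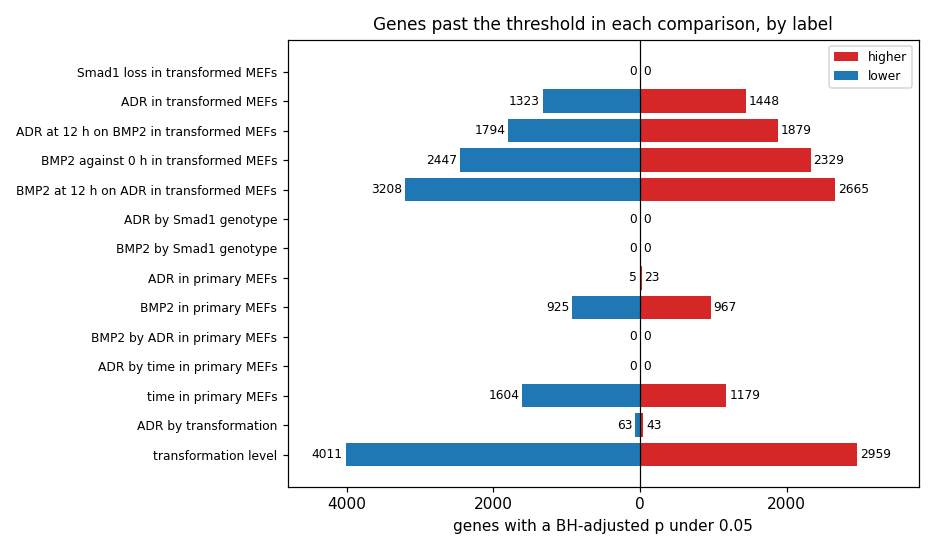
Number of genes with a BH-adjusted p under 0.05 in each of the 14 comparisons, with genes lower to the left and higher to the right. The level difference between the 2 sets gave 6970 genes, BMP2 on ADR 5873, and the 4 interactions within a set and the Smad1 genotype 0.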

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

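The tests of normalization, of mixed RNA, of exchanged labels and of the usual BMP2 targets were chosen after the markers were seen, while that of another cell line and the splits of the arrays were chosen before.

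Marker and response genes do not follow the labels of the 2 sets of arrays. Fibroblast genes differed by a median of 4.54 on the log2 scale in the deposited signals, between the Smad1f/f arrays and those labelled primary before any normalization, which argues against normalization as the cause. 16 list members were detected on all 8 arrays labelled transformed and on none labelled primary. Fibroblast RNA mixed into all 8 arrays would give the same, so this cannot be told apart from a difference of the cells, though mixing would not remove these genes from the arrays labelled primary. 2 of Id1, Id2 and Id3 were significantly lower with the BMP2 label of the primary set, while Id3 did not pass. For these genes, that argues against right labels with a usual BMP2 response. The BMP target list as a whole went both ways there, with Dlx2 higher, and Id1 did not pass in 1 fit of all 16 arrays. An exchange of the labels of the 2 sets stays open as a hypothesis drawn from the same data. At the preset correlation 8 of 8 list tests went as it needs. Among them were BMP targets higher with the Smad1-/- label and with the ADR label of the primary set, p53 targets higher at 16 h, and fibroblast genes higher on the Smad1f/f arrays. With an estimated correlation only the fibroblast list passed among the lists that had to be higher. That test had 10 residual degrees of freedom for the fibroblast list and 3 for the others, so it does not weigh them alike. The other tests needed only that a list was not higher. The Smad1 probe cannot decide the question. Its signal was higher by 0.62 ± 0.083 in 4 of 4 pairs with the BMP2 label of the primary set. An exchange in the order of the samples would put the Smad1-/- label there. But the probe showed no loss under the given labels either. On the Smad1-/- arrays it read 8.36, 8.78, 8.93 and 9.14, against 8.86, 8.75, 8.73 and 8.83 on the matched Smad1f/f arrays. Whether it lies in the deleted part is not known. Whether the BMP2 arrays labelled primary come from another cell line stays open, since 0 Y-linked genes with a probe were detected on any array labelled primary and Xist has no probe. Eif2s3y, a Y-linked gene singled out after its values were seen, was detected on all 8 arrays labelled transformed and on 0 labelled primary, so the sets also differ in a Y-linked gene, and a biological cause of the differences was not tested.

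The response to the ADR label differed between the sets, by the test of the difference itself, for 106 genes. Time is part of this difference, since on the arrays labelled transformed the pairs without BMP2 set 12 h against 0 h. 1 of 35 splits gave as many genes, the real one, and the highest of the others gave 0. The fits of the other splits left out the real difference, which added to their spread, so this test cannot exclude a random grouping. The differences of named genes were 1.62 for Uap1l1, 1.30 for Ndrg1, 1.30 for Dbp, 1.10 for Mmp11, 1.06 for 1700088E04Rik and 0.97 for Fam167a. On the other side were -1.67 for Mmp3, -1.38 for Tnnt2, -1.32 for Sprr2k, -1.21 for Dlgap5, -1.21 for Ankrd1, -1.17 for Ndc80, -1.14 for Ppbp and -1.10 for Dhx9. Probes without a gene name passed as well: ILMN_2736489 at 1.25, ILMN_1243921 at 1.17, ILMN_2725927 at 1.06 and ILMN_3161105 at 1.00 were higher and ILMN_2747811 at -1.41 and ILMN_2649610 at -1.09 lower. Of all these only Uap1l1, Dbp, Mmp3, Tnnt2, Sprr2k, Ndc80, Ppbp, Dhx9 and ILMN_2747811 passed without each array in turn, and without a term for a different BMP2 response in the sets only Uap1l1 did.

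Lists also differed between the sets in their response to the ADR label, by camera at the preset correlation. The medians were 0.14 for p53 targets, -0.68 for G1/S genes, -0.59 for G2/M genes, 0.48 for histone genes, -0.18 for DNA repair genes, 0.50 for interferon genes, 0.20 for stress genes and 0.77 for epithelial markers. On the arrays labelled transformed these responses were uneven. Without BMP2, where 12 h is set against 0 h, list means moved by 0.011 and -0.023 for p53 targets, -0.013 and 0.033 for histone genes, 0.12 and -0.012 for interferon genes and 0.056 and -0.072 for epithelial markers in the Smad1f/f and Smad1-/- pairs, and with BMP2 by 0.43 and 0.43, 0.76 and 0.70, 0.87 and 0.69 and 1.23 and 1.24. Stress genes moved by 0.37 and 0.35 without BMP2 and by 0.022 and -0.012 with it. No list kept its call with an estimated correlation, where the lowest was adjusted p = 0.114. The stress list also lost its preset call without the untreated Smad1f/f array, at a median of 0.29, and without the Smad1f/f ADR array, at 0.20.

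Within sets, BMP targets differed by genotype in the response to the ADR label (0.60) and to BMP2 (-0.38). The osteoblast genes, a list that shares members with the BMP list, differed in that to the ADR label (0.24). On the arrays labelled primary BMP targets responded differently to BMP2 with and without ADR (-0.32). Each of these 4 was past the threshold at the preset correlation and none with an estimated one, and no single gene passed. The estimated test had 2 or 3 residual degrees of freedom here, which leaves it little power.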

How the results depend on the processing

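All settings here were chosen before the data were examined, except log2 of the deposited signals for the fibroblast list. No paired analysis was possible because the labels name no pairs of samples, so contrasts were matched only on the other factors, and the slide block was not run because no slide is named. The fits have 2 to 10 residual degrees of freedom, and a lone array is assumed to vary like the others.

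Counts of genes past the threshold moved by over 1.5 times as follows. With a log2 change of at least 1, ADR on arrays labelled transformed gave 87, ADR on BMP2 gave 579, BMP2 against 0 h gave 1243, BMP2 on ADR gave 1890, ADR on arrays labelled primary gave 7, BMP2 on arrays labelled primary gave 155, time gave 101, ADR by transformation gave 23 and the level difference gave 2504. With the authors' values, Smad1 loss gave 10, ADR on arrays labelled primary 75, time 4353 and ADR by transformation 512. With a robust trend, Smad1 loss gave 5, ADR on arrays labelled primary 88 and ADR by transformation 308. In the joint or reduced fits, Smad1 loss gave 25, ADR by genotype 1, ADR on arrays labelled primary 43, ADR by transformation 1 and the level difference 4464. Without background correction and with median scaling, ADR on arrays labelled primary gave 82 and 54, and ADR by transformation 299 and 300. With detection on every array these 2 gave 43 and 269, and the level difference 4533, where fewer genes were tested. The other causes were not tested.

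Leaving out 1 array gave 0 to 0 for Smad1 loss, 1638 to 2025 for ADR on arrays labelled transformed, 2004 to 3614 for ADR on BMP2, 3377 to 4783 for BMP2 against 0 h, 4615 to 5764 for BMP2 on ADR, 0 to 1 for ADR by genotype, 0 to 0 for BMP2 by genotype, 2 to 9 for ADR on arrays labelled primary, 1160 to 1299 for BMP2 on arrays labelled primary, 0 to 0 for BMP2 by ADR, 0 to 0 for ADR by time, 1658 to 1856 for time, 16 to 365 for ADR by transformation and 6336 to 6992 for the level difference. In direction, endothelial markers with BMP2 on ADR went to -0.18 with detection on every array, Ski with time to -0.026 with the authors' values, and Fbln2 with ADR on arrays labelled primary ranged from -0.12 to 0.63 over the arrays left out, and the cause was not tested. Of gene values under other settings 7853 kept their call or lack of a call, 372 lost the call and 41 gained it, and of list values 2048, 13 and 35. Of the 372 losses 231 came from the log2 change of at least 1, which can only remove calls. With an array left out 8081 gene values kept their call or lack of a call, 661 lost the call and 25 gained it, and of list values 2350, 28 and 44. A change of sign was counted only where the value passed under the main or the other setting. The fibroblast list kept its direction in log2 of the deposited signals. Signal over background limits genes near the detection limit, whose folds are bounds.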

Other observations

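The splits of the arrays were planned before the data were examined, and no test here was chosen after a result was seen.

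Markers of macrophages, endothelium, muscle and nerve were measured to look for other cell types. On the arrays labelled transformed Smad1f/f against those labelled primary, Laptm5, a lysosomal protein of blood cells, was at least 8.78-fold higher and Lyz2, lysozyme of macrophages, at least 2.50-fold. 7 of 10 macrophage and blood markers were higher and 0 lower (median 0.58, or 0.48 with undetected genes at their bounds, adjusted p = 0.00175, or adjusted p = 0.0410 with an estimated correlation), with 7 higher and 0 lower when adjusted over the list alone. Acta1, skeletal muscle actin, was at least 12.9-fold higher, and 6 of 8 muscle markers were higher and 1 lower (median 0.62, adjusted p = 0.0249, or adjusted p = 0.0999 with an estimated correlation), with 6 higher and 1 lower when adjusted over the list alone. Of 9 endothelial markers 4 were higher and 2 lower (median 0.59, or 0.58 with undetected genes at their bounds, adjusted p = 0.499, or adjusted p = 0.721 with an estimated correlation), with 4 higher and 2 lower when adjusted over the list alone. The neural and adipocyte markers gave 3 higher and 1 lower of 7, with a median of -0.047 and a mean of 0.18 of opposite sign (adjusted p = 0.677, or adjusted p = 0.721 with an estimated correlation), and Lpl, lipoprotein lipase, differed by 1.70 ± 0.18. Epithelial markers went both ways, 2 higher and 3 lower of 8, with a median of 0.30 and a mean of -0.70 (adjusted p = 0.744, or adjusted p = 0.920 with an estimated correlation), with Krt7, a keratin of simple epithelia, at 2.41 ± 0.48 and Esrp1, an epithelial splicing factor, at least 6.47-fold lower.

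With BMP2 on ADR on the arrays labelled transformed, epithelial and endothelial markers moved. Krt19, a keratin of simple epithelia, was at least 6.25-fold higher and Krt7 rose 9.31-fold, and 6 of 7 epithelial markers rose and 1 fell (median 2.36, or 1.92 with undetected genes at their bounds, adjusted p = 0.00533, or adjusted p = 0.161 with an estimated correlation), with 6 higher and 1 lower when adjusted over the list alone. Mmrn2, an endothelial matrix protein, rose 13.1-fold, and 6 of 9 endothelial markers rose and 2 fell (median 0.41, or 0.22 with undetected genes at their bounds, adjusted p = 0.0493, or adjusted p = 0.210 with an estimated correlation), with 6 higher and 2 lower when adjusted over the list alone, and this preset call ended without the untreated Smad1f/f array and without the untreated Smad1-/- array, at an unchanged median of 0.41, and with no detection filter, at 0.11. With detection on every array the median turned to -0.18. Cd14, a receptor of monocytes, was at least 7.27-fold higher, and 5 of 10 macrophage and blood markers rose and 1 fell (adjusted p = 0.0771, or adjusted p = 0.464 with an estimated correlation), with 5 higher and 1 lower when adjusted over the list alone. On the arrays labelled primary the endothelial list had a median of -0.21 with the ADR label (adjusted p = 0.00487, or adjusted p = 0.544 with an estimated correlation), with 0 higher and 0 lower when adjusted over the list alone. That call ended without the BMP2 array at 8 h, at -0.17, and without the untreated array at 16 h, at -0.18.

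Other splits of the same arrays into groups of the same sizes as the real ones were counted for each comparison with at least 3 arrays a side. For BMP2 and for time on the arrays labelled primary, 1 of 35 splits, the real one, gave as many genes, 1892 and 2783 against at most 759 and 502 in the others. In every other split the fit left out the real factor, so its effect added to the spread and lowered the counts. The test therefore cannot exclude a random grouping. The same holds for the level difference between the sets, where 1 of 100 splits gave as many and the real count of 6970 stood against 3051. These splits regrouped the Smad1f/f arrays and those labelled primary, with the Smad1-/- arrays kept apart. All but the real split were drawn at random among those that did not take all arrays of a time point. For the ADR label on the arrays labelled transformed 2 of 35 splits gave at least the real 2771, and the other, which follows the BMP2 label, gave 4986. That label is a factor of the design, and the remaining 33 splits gave at most 3, in fits that left out the ADR label. A random grouping stays open. For the ADR label on the arrays labelled primary 3 of 35 gave at least 28, with 2592 for the split that follows time, 1742 for the one that follows the BMP2 label and at most 0 in the remaining 32. Where no gene passed, every split gave as many, 35 of 35 each: the highest others gave 6310 for Smad1 loss, 6432 for the genotype interaction with the ADR label and as many for that with BMP2, 2844 for BMP2 by ADR and 2783 for ADR by time. Those high counts come from the splits that follow the BMP2 label on the arrays labelled transformed and time on those labelled primary. Both are factors of the design, so the counts restate the responses given above. Comparisons of 2 arrays against 2 were not tested by splits.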
